A study of Homo sapiens with 6 samples.

How the data were processed

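RNA was taken from the TC32 Ewing sarcoma cell line 48 h after transfection with a control siRNA (siNeg), an siRNA against EWSR1 (siEWSR1) or an siRNA against FLI1 (siFLI1), and 2 libraries per group were sequenced, 6 in all. The deposited files hold gene-level FPKM values made by the authors, fragment counts scaled to transcript length and library size, with the lower and upper bound of a 95% interval for each. TopHat2 2.0.13, Cufflinks, Cuffdiff and the human genome build hg19 are named, per the submitters' processing notes. The gene annotation, the strand setting, the library kit and the treatment of reads that map to several places are not given in the sources used here. FPKM is relative to each library's total, so a few very abundant RNAs can shift all others, and reads of near-identical genes (histones, metallothioneins) or of overlapping and antisense genes cannot be told apart. Gene-level FPKM also adds reads of the normal transcripts of EWSR1 and FLI1 to those of a fusion transcript.

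Each file listed 27442 rows for 26931 gene symbols, and 380 symbols stood on more than 1 row, whose FPKM values were summed. Rows were joined by gene and position because their order differed between files. Gene starts were converted to count from 1: of 23769 symbols also found in a RefSeq table of another build, 6149 had the same length if the file counted from 0 and 579 if it counted from 1. No coordinate was taken from that table. Across libraries, 13 rows carried a failed status in at least 1 library.

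FPKM files give no fragment counts. If the distance from a value to its deposited bounds is read as 2 times the FPKM divided by the square root of the fragments, the genes added up to 16298374 and 15284159 fragments in the siNeg libraries, 16050052 and 15316402 with siEWSR1, and 15159073 and 15637129 with siFLI1. The values of genes that this reading gives 1 fragment put each library's depth at 0.908 to 1 times that of siNeg replicate 1. Between 36.2% and 38.8% of low genes came out as whole fragments within 0.01, so counts were not recovered and no count model was used. Small RNAs held 32.5% to 49.9% of the summed FPKM of a library, as their short length inflates the unit.

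Genes with an FPKM of at least 1 in at least 2 of the 6 libraries were tested, 13043 in all. Values were analysed as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level and 1 fit over all 6 libraries (3 residual degrees of freedom, 3.39 prior). The comparisons were siEWSR1 with siNeg, siFLI1 with siNeg and siEWSR1 with siFLI1. P-values were adjusted over genes by Benjamini-Hochberg, with a threshold of 0.05, and all are two-sided. Folds are on the log2(FPKM + 0.5) scale and understate the change of low genes. Errors of log2 changes are standard errors from the fit. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

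Before the data were examined, 20 gene lists were fixed from general knowledge: EWS-FLI1-activated and EWS-FLI1-repressed targets, extracellular matrix, actin cytoskeleton and focal adhesion, DNA replication, mitosis, p53 targets, interferon response, serine synthesis and ATF4 targets, cholesterol synthesis, hypoxia and glycolysis, neural and neuroendocrine genes, ETS transcription factors, FET family and splicing factors, IGF signalling, ribosomal proteins, replication-dependent histones, and markers of epithelial, blood and endothelial cells. Each was tested against the other genes with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over the 20 lists. With all libraries and the settings above, none of the calls made by camera at the preset correlation held with the estimated one, and its adjusted p is given beside these. The estimated correlation was not combined with the other alternatives.

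Named genes followed a rule also fixed beforehand. It takes EWSR1 and FLI1; the 5 highest and 5 lowest changes per comparison among called genes with a mean FPKM of at least 5 in the higher group, no overlap between the groups, an OK status in all libraries and 1 row; the 5 higher and 5 lower with both siRNAs; up to 3 called members per list and siRNA; and up to 3 genes called in opposite directions. Small RNAs recognised by a fixed set of symbol prefixes, which did not take in the variant U1 gene RNVU1-8, and mitochondrially encoded and Y-linked genes and XIST were left out of the parts that rank all genes. Genes that the rule or the lists take but whose results are withheld are not reported here. Other genes named here were chosen after their values were seen, and are identified as such.

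The fit was tested on simulated data with 200 of 13043 genes changed. In the simulated siEWSR1 against siNeg comparison it recovered 82.1% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, and 3.1% of its 191 calls were false. Chance agreement between the siRNA comparisons, which share the siNeg libraries, was simulated in 20 runs with unchanged groups. The alternatives were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, no variance trend, a robust trend, only the 2 groups compared, the replicate number as a block, a minimum log2 change of 1, rows with an OK status throughout, an estimated inter-gene correlation, and each library left out. A fit restricted to genes that overlap no other expressed gene and are no small RNA was added after seeing the data, as was a split that gives 1 siNeg library to each siRNA comparison. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.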

Results

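Gene expression was measured by RNA sequencing in TC32, a cell line from Ewing sarcoma, a tumour of bone and soft tissue in children and young adults. Most such tumours carry a fusion that joins the 5′ part of EWSR1, which encodes an RNA-binding protein of the FET family, to the 3′ part of FLI1, which encodes a transcription factor of the ETS family. Cells received siNeg, siEWSR1 or siFLI1, and 2 libraries per group were taken 48 h later, to profile knockdown aimed at the fusion through either partner gene. The 6 libraries had 12079 to 12741 genes at an FPKM of 1 or more and similar depth, 15159073 to 16298374 fragments as implied by the deposited intervals. Across genes, log2 values correlated at 0.979 between the siNeg libraries, 0.971 between the siEWSR1 libraries and 0.974 between the siFLI1 libraries. Libraries of different siRNAs against the fusion partners correlated at 0.972 to 0.976 and either with siNeg at 0.894 to 0.913 (genes are not independent replicates).

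EWSR1 (hg19, chromosome 22, 29663998 to 29696515) stood at 46.5 and 47.2 FPKM in the siNeg libraries, 34.6 and 32.3 with siEWSR1, and 51.2 and 50.2 with siFLI1. Its log2 change with siEWSR1 was -0.48 ± 0.06 (SE, adjusted p = 0.000444), a 1.39-fold fall, and with siFLI1 0.11 ± 0.06 (adjusted p = 0.11). FLI1 (chromosome 11, 128556430 to 128683162) stood at 10.9 FPKM in both siNeg libraries, 10.4 and 10.6 with siEWSR1, and 8.98 and 8.56 with siFLI1. FLI1 fell by 0.29 ± 0.06 on the log2 scale with siFLI1 (adjusted p = 0.00423), and its change with siEWSR1 was -0.04 ± 0.06 (adjusted p = 0.534). Each gene was thus lower in both libraries of its own siRNA than in both siNeg libraries. With quantile normalization EWSR1 passed the threshold as higher with siFLI1, at 0.20 (adjusted p = 0.0107). These values sum normal and fusion transcripts, and the region each siRNA targets is not given in the sources used here.

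**Figure D1:**
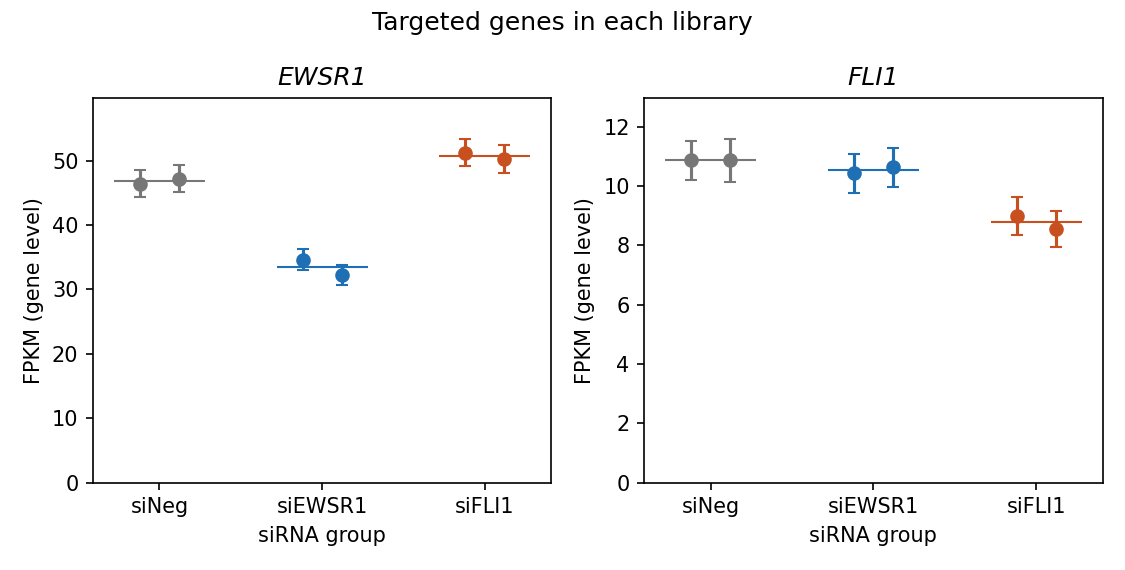
FPKM of EWSR1 and FLI1 (y axis, from 0) in each library by siRNA group (x axis); points are libraries, vertical bars the deposited 95% intervals and horizontal lines group means. EWSR1 lies at 32.3 and 34.6 FPKM with siEWSR1 against 46.5 and 47.2 with siNeg, and FLI1 at 8.56 and 8.98 with siFLI1 against 10.9 with siNeg.

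With siEWSR1, 25 of 27 measured extracellular matrix genes rose, while 37 of 37 mitosis genes, 24 of 26 serine synthesis and ATF4 target genes and 33 of 35 EWS-FLI1-activated targets fell (limma, adjusted p under 0.05). IGFBP3, which encodes a binding protein for insulin-like growth factors and is a known EWS-FLI1-repressed gene, went from 1.72 ± 0.04 to 527 ± 46.8 FPKM (SD, n = 2), a 238-fold rise. MGP, a matrix protein that inhibits calcification, rose 224-fold to 336 ± 47.6 FPKM, and the imprinted non-coding RNA H19 rose 193-fold to 107 ± 6.41 FPKM. SULF2, an extracellular sulfatase acting on heparan sulfate, rose 76.7-fold, and TGM2, a protein cross-linking enzyme, 68.8-fold. CHAC1, a glutathione-degrading enzyme, fell 28.5-fold from 39.2 ± 4.57 to 0.895 ± 0.161 FPKM. In all, 4331 genes were higher and 4041 lower of 13043 tested, of which 1032 and 599 changed at least 2-fold and 260 and 41 at least 4-fold (limma, adjusted p under 0.05).

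Of 35 measured EWS-FLI1-activated targets, 33 fell and 0 rose with siEWSR1, with a median log2 change of -0.97 (camera adjusted p = 1.45e-10; adjusted p = 0.575 with an estimated correlation). NR0B1, a nuclear receptor that EWS-FLI1 activates through GGAA repeats, fell from 219 ± 21 to 62.5 ± 21.9 FPKM. CCK, the gene for the peptide cholecystokinin, fell from 57.0 ± 5.02 to 15.9 ± 2.99 FPKM, and PAPPA, a protease for IGF-binding proteins, from 22.2 ± 1.40 to 6.58 ± 2.01 FPKM, although PAPPA overlaps its antisense gene. Of 29 measured EWS-FLI1-repressed targets, 25 rose and 2 fell, with a median of 1.32 (adjusted p = 4.02e-08; adjusted p = 0.351 with an estimated correlation). DKK1, a secreted WNT inhibitor, rose from 0.89 ± 0.12 to 39.6 ± 4.30 FPKM, and THBS1, a matrix glycoprotein, from 0.017 ± 0.007 to 6.0 ± 0.93 FPKM. The 2 that fell, named after their values were seen, were LOX, a collagen cross-linking enzyme (-0.34), and ITGA5, a fibronectin receptor subunit (-0.34).

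Among 27 measured extracellular matrix genes, 25 rose and 1 fell with siEWSR1, with a median log2 change of 1.49 (camera adjusted p = 6.63e-11; adjusted p = 0.478 with an estimated correlation). The one that fell, chosen after its values were seen, was PLOD2 (-0.49), a lysyl hydroxylase of collagen. TIMP3, an inhibitor of matrix proteases, rose from 0.27 ± 0.08 to 43.6 ± 4.98 FPKM, LAMA4, a laminin chain, from 3.08 ± 0.42 to 47.8 ± 2.46, and COL1A1, a chain of type I collagen, from 7.5 ± 0.84 to 100.4 ± 2.00. Of 33 actin cytoskeleton and focal adhesion genes, 14 rose and 7 fell, and the list as a whole missed the threshold (adjusted p = 0.17; adjusted p = 0.657 with an estimated correlation) but was called as higher with quantile normalization (0.012) or a mean FPKM of at least 5 (0.0373). ITGA3, an integrin chain, rose 4.83-fold, TPM1, a tropomyosin, 4.3-fold and TAGLN, an actin-binding protein, 3.02-fold. Of 13 IGF signalling genes, 9 rose and 3 fell (adjusted p = 0.0402; adjusted p = 0.657 with an estimated correlation). IGFBP5 rose from 208 ± 11.2 to 1298 ± 129 FPKM, IGFBP6 4.59-fold, and IGFBP7, which overlaps POLR2B, 3.82-fold. STC2 (-1.93), IRS1 (-0.75) and IRS2 (-0.32) fell, named after their values were seen. The IGF list's call ended without siEWSR1 replicate 1 or 2 (adjusted p = 0.0603 and 0.0925), with quantile normalization (0.0516), with no variance trend (0.0553) and without overlapping genes (0.171).

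All 37 mitosis genes fell with siEWSR1, with a median log2 change of -1.35 (camera adjusted p = 2.09e-15; adjusted p = 0.575 with an estimated correlation). KIF2C, a microtubule-depolymerizing kinesin, fell from 131 ± 0.74 to 32.3 ± 4.99 FPKM, UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, from 301 ± 0.75 to 90.0 ± 25.1, and AURKB, a mitotic kinase, from 114 ± 0.51 to 34.6 ± 5.50. Of 38 DNA replication genes 31 fell and 0 rose, with a median of -0.54 (adjusted p = 9.54e-08; adjusted p = 0.657 with an estimated correlation). CDT1, a replication licensing factor, fell 2.69-fold, PRIM1, a primase subunit, 2.53-fold, and RFC4, a clamp loader subunit that overlaps EIF4A2, 2.28-fold. Of 8 measured replication-dependent histone genes, 6 rose and 0 fell, with a median of 2.08 (adjusted p = 0.00179; adjusted p = 0.478 with an estimated correlation). HIST1H2AC rose from 2.41 ± 0.53 to 30.3 ± 3.13 FPKM, HIST1H2BD 8.09-fold and HIST1H2BK 5.7-fold, with reads of near-identical histone copies not separable. With low genes kept in the test the histone median was 0.26 and the call was lost (adjusted p = 0.0697).

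Of 26 serine synthesis and ATF4 target genes, 24 fell and 1 rose with siEWSR1, with a median log2 change of -1.59 (camera adjusted p = 5.16e-11; adjusted p = 0.478 with an estimated correlation). TRIB3, a stress-induced pseudokinase, fell from 134 ± 24.4 to 11.0 ± 2.23 FPKM and ASNS, asparagine synthetase, from 202 ± 30.4 to 19.1 ± 1.90. Outside the list, CTH, a cysteine-producing enzyme, fell 11.9-fold, PCK2, a mitochondrial gluconeogenic enzyme, 11-fold and the non-coding FLJ46906 12.7-fold. The member that rose, named after its values were seen, was HSPA5 (0.43), a chaperone of the endoplasmic reticulum. Of 26 hypoxia and glycolysis genes 20 fell and 3 rose, with a median of -0.78 (adjusted p = 0.00226; adjusted p = 0.657 with an estimated correlation). ALDOC, a glycolytic aldolase, fell 4.38-fold, whereas NDRG1, a hypoxia-induced gene, rose 3.35-fold. ADM (1.30) and EGLN3 (0.66) rose too, with these values looked up afterwards. CA9, a carbonic anhydrase, fell by 2.13 ± 0.65 on the log2 scale (adjusted p = 0.0256), a call lost without siEWSR1 replicate 2 (-1.22, adjusted p = 0.0719) or either siNeg library (adjusted p = 0.0885 and 0.082), with a robust variance trend (0.124) and with no filter (0.0864). Of 24 cholesterol synthesis genes 16 fell and 1 rose, with a median of -0.52 (adjusted p = 0.00198; adjusted p = 0.657 with an estimated correlation). SREBF2, a transcription factor of the pathway, fell 2.16-fold, MSMO1 1.98-fold and FDFT1 1.93-fold, and CYP51A1, chosen after its values were seen, rose by 0.30.

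The remaining lists were not called with siEWSR1. Of 24 p53 targets 12 rose and 7 fell (camera adjusted p = 0.258): CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 5.13 ± 0.15 to 44.1 ± 1.10 FPKM and TP53I3, which overlaps FAM228B, 4.77-fold, whereas PMAIP1, a pro-apoptotic gene, fell 4.21-fold. Of 23 interferon response genes 12 rose and 4 fell (adjusted p = 0.151), with IFI6 up 2.46-fold and IRF9 2.28-fold. Of 15 neural and neuroendocrine genes 7 rose and 6 fell (adjusted p = 0.824), with the adhesion molecule L1CAM up 5.84-fold, the neurotrophin receptor NGFR up 2.22-fold and the enolase ENO2 down 2.45-fold. Of 14 ETS transcription factors 7 rose and 4 fell (adjusted p = 0.278), with ETS2 up 3.72-fold, ELK3 up 2.05-fold and ETV1 down 2.47-fold. Of 35 FET family and splicing factors 14 rose and 8 fell (adjusted p = 0.502), with SRSF6 up 1.63-fold and SRSF7 down 1.71-fold; quantile normalization called this list as higher (adjusted p = 0.00471), against an adjusted p = 0.702 with an estimated correlation and no such normalization. Of 38 ribosomal protein genes 2 rose and 6 fell (adjusted p = 0.254), with RPS27 up 1.29-fold and RPL10A down 1.27-fold, the latter not called with quantile normalization (-0.12, adjusted p = 0.116). Few markers of other cell types were measured: 4 epithelial (3 higher, 1 lower, adjusted p = 0.397), 2 of blood cells (1 higher, adjusted p = 0.502) and 1 endothelial (lower, adjusted p = 0.502). CD34 rose from 0.044 ± 0.018 to 1.68 ± 0.35 FPKM, CLDN4 from 0.24 ± 0.02 to 1.40 ± 0.01, and ESRP1 fell from 1.82 ± 0.83 to 0.073 ± 0.001. KRT14 was called higher at 0.50 but stood at -0.01 under quantile normalization, and EGFL7, called lower at -0.40, lost its call without siNeg replicate 1 (adjusted p = 0.089), siNeg replicate 2 (0.16), siEWSR1 replicate 2 (0.0988, at a change of -0.18), siFLI1 replicate 1 (0.0671) or siFLI1 replicate 2 (0.0686), and in 4 other settings (0.0551 to 0.109), and stood at -0.62 without siEWSR1 replicate 1. Adjusted over the list alone, 32 DNA replication and 25 serine and ATF4 genes were lower, 2 cholesterol genes were higher and 2 ribosomal protein genes were lower, and counts of the other lists were the same as over all genes.

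With siFLI1, MGP rose 278-fold to 416 ± 18 FPKM, IGFBP3 199-fold to 441 ± 22.2, H19 174-fold to 96.6 ± 10.9, TGM2 103-fold to 74.0 ± 7.58, and KRT15, an epithelial keratin, 84.5-fold from 0.17 ± 0.04 to 55.7 ± 0.47. CHAC1 fell 22-fold, FLJ46906 12.3-fold, CTH 12-fold, TRIB3 10.9-fold and MYEOV, a gene first found in myeloma, 11.6-fold. In all 4656 genes were higher and 3861 lower, with 1215 and 599 at least 2-fold and 331 and 38 at least 4-fold (limma, adjusted p under 0.05).

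Of the 35 EWS-FLI1-activated targets, 30 fell and 1 rose with siFLI1, with a median log2 change of -0.99 (camera adjusted p = 9.22e-11; adjusted p = 0.541 with an estimated correlation). NR0B1 stood at 62.7 ± 8.88 FPKM, CCK at 15.3 ± 1.31 and PAPPA at 5.10 ± 1.04, each called lower than with siNeg. The member that rose, named after its values were seen, was EGR2 (0.31), a growth factor-induced transcription factor. Of the 29 repressed targets 24 rose and 2 fell, with a median of 1.57 (adjusted p = 4.92e-08; adjusted p = 0.357 with an estimated correlation), with rises of IGFBP3, DKK1 (41.6-fold) and CDKN1A (14.2-fold, to 79.4 ± 6.16 FPKM). Of the 27 matrix genes 25 rose and 1 fell, with a median of 1.96 (adjusted p = 9.22e-11; adjusted p = 0.485 with an estimated correlation). PLOD2 again fell (-0.56), as did the repressed targets ITGA5 (-0.25) and EPHA4 (-0.27), an ephrin receptor, all chosen after their values were seen. TIMP3 rose 59.5-fold, COL1A1 17.5-fold and LAMA4 13.9-fold. Of the 33 actin and adhesion genes 22 rose and 6 fell, with a median of 0.29 (adjusted p = 0.00869; adjusted p = 0.546 with an estimated correlation). TPM1 rose 7.05-fold to 95.1 ± 0.32 FPKM, ITGA3 6.61-fold and TAGLN 3.74-fold.

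All 37 mitosis genes fell with siFLI1, with a median of -1.38 (camera adjusted p = 1.53e-16; adjusted p = 0.541 with an estimated correlation), among them KIF2C (4-fold), NEK2 (3.78-fold) and ASPM (3.58-fold). Of the 38 DNA replication genes 31 fell and 1 rose, with a median of -0.57 (adjusted p = 9.46e-08; adjusted p = 0.546 with an estimated correlation). The one that rose, named after its values were seen, was CCNE2 (0.22), a cyclin of the G1/S transition. Of the 8 histone genes 5 rose and 0 fell, with a median of 1.91 (adjusted p = 0.0224; adjusted p = 0.541 with an estimated correlation), and with low genes kept the histone median was 0.29 and the call was lost (adjusted p = 0.166). Of the 26 serine and ATF4 genes 24 fell and 1 rose, with a median of -1.45 (adjusted p = 9.22e-11; adjusted p = 0.541 with an estimated correlation), and ASNS stood at 19.7 ± 1.77 FPKM. Of the 26 hypoxia and glycolysis genes 19 fell and 3 rose, with a median of -0.76 (adjusted p = 0.00102; adjusted p = 0.636 with an estimated correlation), and ADM, which encodes the vasodilator adrenomedullin, rose 3.98-fold. CA9 fell by 2.00 ± 0.65 (adjusted p = 0.0321), a call lost without siFLI1 replicate 2 (-1.31, adjusted p = 0.169), siNeg replicate 1 (0.103) or siNeg replicate 2 (0.0968), with a robust variance trend (0.141), with no filter (0.0994) and with a pseudocount of 0.1 (0.0587). Of the 24 cholesterol genes 12 fell and 2 rose, with a median of -0.29 (adjusted p = 0.0224; adjusted p = 0.722 with an estimated correlation); the median was -0.43 without siNeg replicate 1, and the call ended without siNeg replicate 2 (median -0.17, adjusted p = 0.0832), with quantile normalization (0.0928) and with a mean FPKM of at least 5 (0.111). LSS, chosen after its values were seen, was among those that rose (0.41). Of the 23 interferon response genes 15 rose and 3 fell, with a median of 0.45 (adjusted p = 0.0242; adjusted p = 0.541 with an estimated correlation), and quantile normalization (adjusted p = 0.0672) or a mean FPKM of at least 5 (0.122) ended this call.

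The lists not called with siFLI1 were p53 targets (11 of 24 higher, 8 lower, camera adjusted p = 0.433), neural genes (6 of 15 higher, 5 lower, adjusted p = 0.986) and ETS factors (7 of 14 higher, 4 lower, adjusted p = 0.559). FET and splicing factors had 12 of 35 higher and 10 lower (adjusted p = 0.986). Their median was 0.03, against 0.041 over all tested genes, and camera's direction was down. IGF signalling had 8 of 13 higher and 2 lower (adjusted p = 0.0932, 0.00133 with a mean FPKM of at least 5, and adjusted p = 0.594 with an estimated correlation over all tested genes), with IGFBP6 up 9.43-fold, IGFBP5 7.72-fold and IGFBP4 4.83-fold. Ribosomal proteins had 1 of 38 higher and 5 lower (adjusted p = 0.327). Epithelial markers had 3 of 4 higher and 1 lower (adjusted p = 0.401), and blood cell markers 1 of 2 higher (adjusted p = 0.204). The endothelial marker EGFL7 was not called (24.6 ± 1.16 FPKM against 25.6 ± 1.34 with siNeg, camera adjusted p = 0.914). KRT14, called higher at 0.51, stood at -0.07 under quantile normalization. Adjusted over the list alone, 16 interferon genes, 8 ETS factors and 2 blood cell markers were higher, and 11 cholesterol, 20 hypoxia and 1 ribosomal protein genes were lower, with the other counts the same as over all genes.

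**Figure D2:**
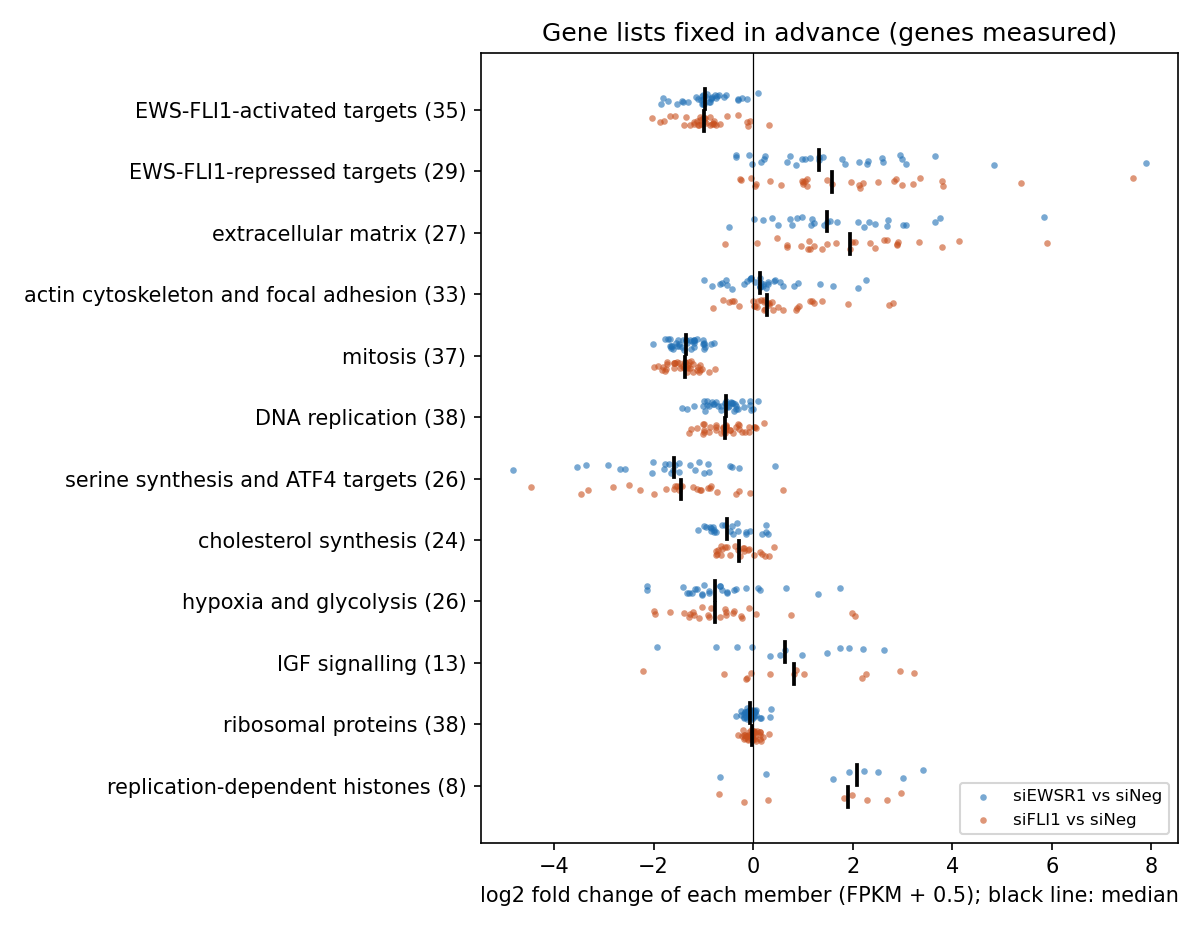
Log2 fold change against siNeg (x axis, on FPKM + 0.5) of each measured member of 12 lists (y axis, number measured in brackets) for siEWSR1 (blue) and siFLI1 (orange); points are genes and black lines list medians. The mitosis genes all lie below 0, with medians of -1.35 and -1.38, and the matrix genes mostly above 0, with medians of 1.49 and 1.96.

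The responses to the siRNAs overlapped: 3901 genes were higher and 3411 lower with both, against 1546 and 1196 for independent lists of those sizes. MGP, IGFBP3, H19, SULF2 and TGM2 led the genes higher with both, and CHAC1, FLJ46906, CTH, TRIB3 and MYEOV those lower with both. Across genes, log2 changes correlated at 0.941 (0.481 in simulations of unchanged groups that share the siNeg libraries), with a covariance of 0.575 against 0.0211 simulated, a difference of 0.554. Signs were the same in 89.9% of genes, against 66.8% simulated. With 1 siNeg library given to each siRNA comparison, a split chosen after seeing the data, the correlation was 0.83 or 0.82, the covariance 0.538 or 0.535 and the share of same signs 87.3% or 86.9%, by which library went to which. In the simulations 0.25 genes on average were called with both in the same direction, against 7312 observed. Those simulations held no real changes. Part of the excess over independent lists may come from the shared siNeg libraries, as the observed count was not repeated with 1 library each. Only 16 genes were called in opposite directions, led by PTGFRN (-0.35 with siEWSR1 and 0.60 with siFLI1), LAMTOR1 (-0.35 and 0.53, overlapping LRTOMT) and RAB34 (-0.39 and 0.35).

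**Figure D3:**
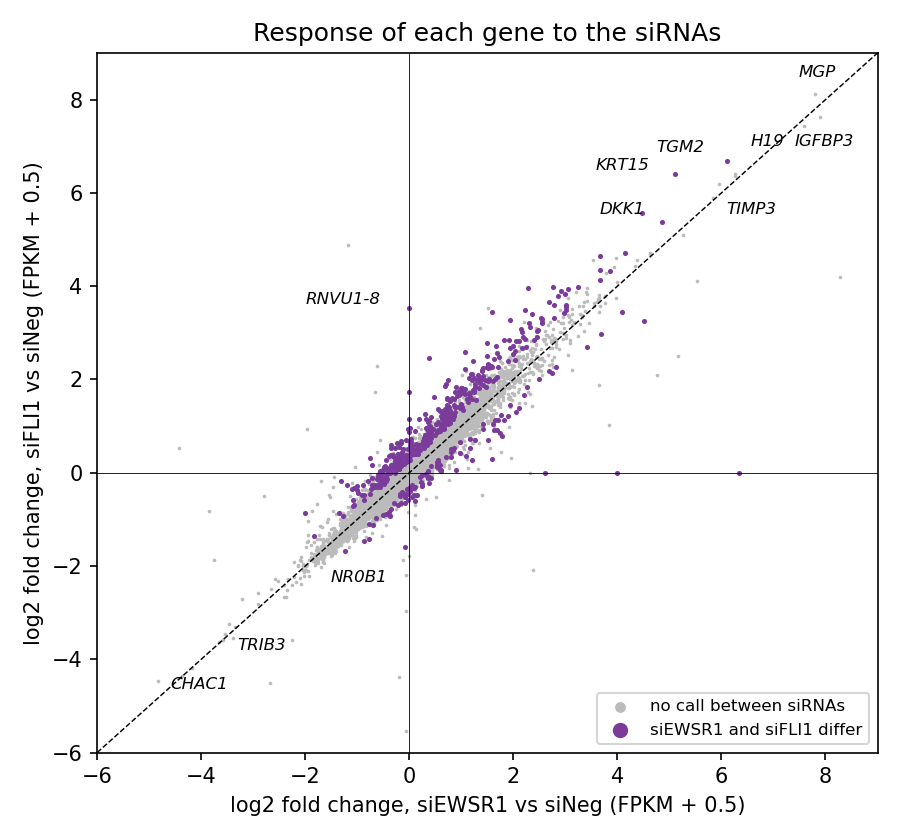
Log2 fold change of each of 13043 genes with siFLI1 (y axis) against that with siEWSR1 (x axis), both against siNeg on FPKM + 0.5; points are genes, purple those called different between the siRNAs, and the dashed line marks equal changes. Points follow the line (correlation 0.941 across genes), and most purple points lie above it, as 401 genes were lower and 103 higher with siEWSR1 than with siFLI1.

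Directly compared, siEWSR1 lay below siFLI1 in 401 genes and above it in 103. KRT15 was at 22.4 ± 3.49 FPKM with siEWSR1 and 55.7 ± 0.47 with siFLI1 (log2 difference -1.30, adjusted p = 0.0059), PLAT, the gene for tissue plasminogen activator, at 2.30 ± 0.47 and 6.47 ± 0.40, and BDKRB1, a bradykinin receptor, at 1.99 ± 0.41 and 5.44 ± 0.31. RNVU1-8, a variant U1 small nuclear RNA, was listed at 0 in all siNeg and siEWSR1 libraries and averaged 5.31 FPKM with siFLI1. It is a short gene (chromosome 1, 146556163 to 146556303), whose length inflates FPKM, so few fragments may set this value. Higher with siEWSR1 were IGDCC4, MT1F (a metallothionein), HIST1H2AC, SLC30A1 (a zinc exporter) and CXCL12 (a chemokine), by 0.75, 0.72, 0.72, 0.71 and 0.71 on the log2 scale. FLI1 differed by 0.25 ± 0.06 (95% interval 0.11 to 0.39, adjusted p = 0.0653) and EWSR1 by -0.59 (adjusted p = 0.00958). The EWS-FLI1-activated targets had 0 of 35 members called, with a median difference of 0.04 (camera adjusted p = 0.0693), which became a call with the list higher in siEWSR1 without siEWSR1 replicate 2 (median 0.175, adjusted p = 1.41e-06) or siFLI1 replicate 1 (0.085, adjusted p = 0.00816) and with quantile normalization (0.101, adjusted p = 0.021). The median was -0.083 without siEWSR1 replicate 1 and -0.012 without siFLI1 replicate 2, neither called (adjusted p = 0.693 and 0.588). With all libraries this list had an adjusted p = 0.873 with an estimated correlation. For its NR0B1 the interval of the difference was -0.59 to 0.51.

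Of the 33 actin and adhesion genes 8 were lower with siEWSR1 than with siFLI1 and 0 higher, with a median difference of -0.16 (camera adjusted p = 9.65e-07; adjusted p = 0.465 with an estimated correlation); TPM1 differed by -0.71 (adjusted p = 0.00442). Of the matrix genes 5 of 27 were lower (adjusted p = 0.00336; adjusted p = 0.677 with an estimated correlation), and of the repressed targets 4 of 29 (adjusted p = 0.00336; adjusted p = 0.465 with an estimated correlation), CDKN1A among them at -0.84. Both of these calls ended without siEWSR1 replicate 1 (adjusted p = 0.0949 and 0.0721), and the median of the repressed targets went from -0.18 to -0.28 without siEWSR1 replicate 2. Adjusted over the list alone, 14 actin, 12 matrix and 11 repressed genes were lower and 3 repressed genes higher. The DNA replication list had a median of -0.003 and a mean of -0.02, with camera's direction up (adjusted p = 0.648). The hypoxia list had a median of 0.006 and a mean of -0.04, also with camera's direction up (0.618). Camera compares a list with the other genes, and the median difference over all tested genes was -0.032. Both lists were called lower without siEWSR1 replicate 1 (medians -0.124 and -0.25) and higher without siEWSR1 replicate 2 (0.101 and 0.22). With all libraries both had an adjusted p = 0.942 with an estimated correlation. FET and splicing factors had a median of 0.002 (camera adjusted p = 0.146, and 0.754 with an estimated correlation). Quantile normalization called this list as higher (0.1, adjusted p = 0.00167), and its median ran from -0.009 to 0.062 as single libraries were left out. ETS factors had a median of 0.057 (adjusted p = 0.158, and 0.814 with an estimated correlation). It was 0.101, called as higher, without siFLI1 replicate 2, but 0.036 without siEWSR1 replicate 2 and -0.013 without siFLI1 replicate 1.

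A fit that leaves out 1 library has fewer residual degrees of freedom, and the direct counts were then 3 higher and 1 lower without siFLI1 replicate 2, 6 and 17 without siFLI1 replicate 1, 11 and 126 without siEWSR1 replicate 2, 107 and 621 without siEWSR1 replicate 1, 15 and 109 without siNeg replicate 1, and 15 and 119 without siNeg replicate 2. The share of higher calls was 20.4%, against 31.0% with median-of-ratios scaling and 37.9% with quantile normalization. Most direct calls were thus lost without either siFLI1 library. Genes not named in the rest of this paragraph, TPM1 and CDKN1A among them, were not looked up one by one in these fits. Without siFLI1 replicate 2 the differences of EWSR1, PLAT, KRT15, BDKRB1 and the 5 genes higher with siEWSR1 missed the threshold, at adjusted p of 0.106 to 0.218, and so did all of these without siFLI1 replicate 1, at 0.0674 to 0.191. Calls were also lost without siEWSR1 replicate 2 for IGDCC4, HIST1H2AC, SLC30A1 and CXCL12 (0.0632 to 0.127), without siEWSR1 replicate 1 for SLC30A1 (0.0589), and without either siNeg library for SLC30A1 and CXCL12 (0.0769 to 0.0866). With no filter PLAT, BDKRB1 and the 5 genes higher with siEWSR1 missed the threshold (0.0563 to 0.118), as did HIST1H2AC, SLC30A1 and CXCL12 with no variance trend or only the 2 groups compared (0.0508 to 0.0912), HIST1H2AC and SLC30A1 with a pseudocount of 0.1 (0.0582 and 0.0527) and BDKRB1 with quantile normalization (0.0503). SLC30A1 stood at 0.51 without siFLI1 replicate 1, while without siFLI1 replicate 2 sizes stayed close or grew, for example -0.61 for EWSR1, -1.29 for KRT15, -1.27 for PLAT, 0.79 for IGDCC4 and 0.92 for SLC30A1.

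**Figure D4:**
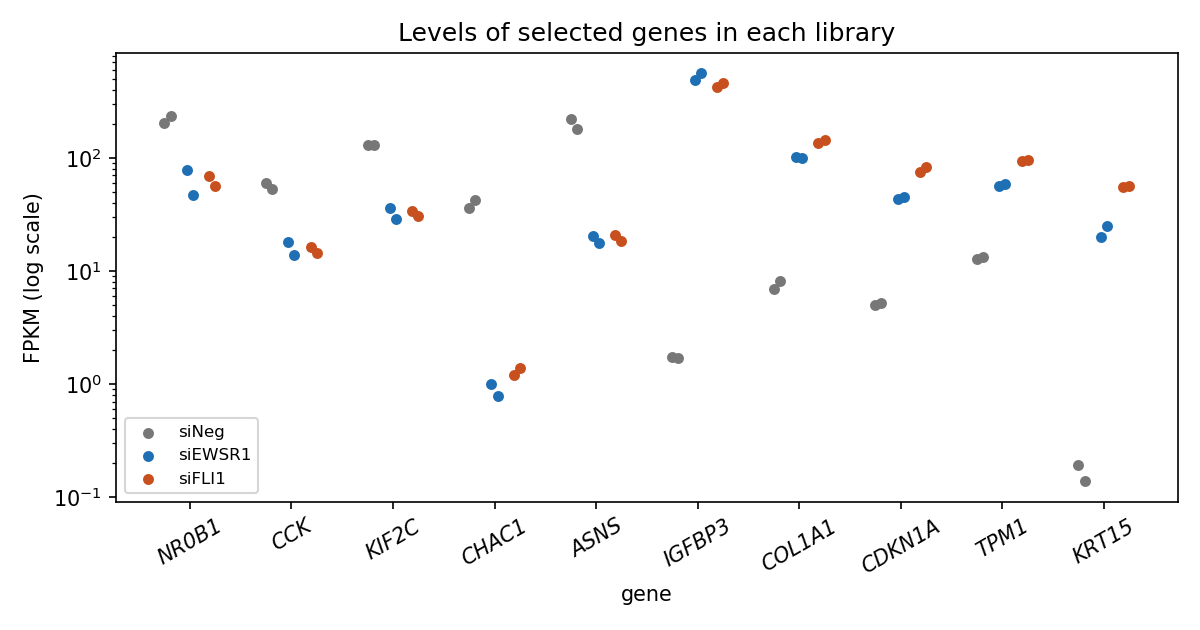
FPKM (y axis, log scale) of 10 genes (x axis) in each of the 6 libraries, coloured by siRNA; each point is a library. NR0B1, CCK, KIF2C, CHAC1 and ASNS lie lower in all 4 siEWSR1 and siFLI1 libraries than in the siNeg libraries and the other 5 genes higher, with TPM1 at 57.8 FPKM on average with siEWSR1 and 95.1 with siFLI1.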

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

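The direct comparison of genes and lists was planned, and of the tests of explanations in this part, all but that of RNAs without a poly(A) tail, whose levels had not been examined, were chosen after the results were seen. Results are listed here because a direct test of siEWSR1 against siFLI1 passed its threshold. Fits without 1 library have fewer residual degrees of freedom, yet their direct calls did not all shrink. Calls were far fewer without either siFLI1 library. They were also fewer without siEWSR1 replicate 2 or a siNeg library, which does not enter the differences, but more numerous without siEWSR1 replicate 1. Without siFLI1 replicate 2 the differences of EWSR1 and KRT15 were -0.61 and -1.29. Nearly all of the gene calls listed here were lost in that fit, and the sizes of most other genes were not looked up. The genes lower with siEWSR1 had log2 differences of -3.54 (RNVU1-8), -1.33 (PLAT), -1.30 (KRT15), -1.26 (BDKRB1), -0.96 (PTGFRN), -0.89 (LAMTOR1), -0.84 (CDKN1A), -0.78 (TP53INP1 and IGFBP4), -0.76 (L1CAM), -0.74 (RAB34), -0.73 (CD34), -0.71 (TPM1), -0.69 (ADM), -0.59 (EWSR1 and TGM2), -0.53 (DKK1 and NGFR), -0.50 (ETS2) and -0.47 (COL1A1). Higher were IGDCC4 (0.75), MT1F (0.72), HIST1H2AC (0.72), SLC30A1 (0.71) and CXCL12 (0.71). The difference of RNVU1-8, a short gene whose length inflates FPKM, may rest on few fragments. Camera compares a list with the other genes, and the median difference over all tested genes was -0.032. Of the lists, the median differences were -0.18 for EWS-FLI1-repressed targets (adjusted p = 0.00336; adjusted p = 0.465 with an estimated correlation), -0.21 for matrix (0.00336; 0.677), -0.16 for actin and adhesion (9.65e-07; 0.465) and 0.057 for mitosis (0.00404; 0.814). They were -0.14 for interferon response (adjusted p = 0.0141; adjusted p = 0.619 with an estimated correlation), -0.14 for serine and ATF4 genes (adjusted p = 0.00841; 0.754), -0.17 for cholesterol synthesis (0.00841; 0.81), 0.23 for histones (0.00102; 0.465) and -0.59 for the 2 measured blood cell markers (0.0341; 0.574), of which 1 was called. With no filter the blood cell median was -0.07 (0.307), and its call also ended with a pseudocount of 0.1 (0.0522) and without overlapping genes (0.0985). The mitosis median was -0.06 (adjusted p = 0.762) without siEWSR1 replicate 1, 0.19 without siEWSR1 replicate 2, 0.10 without siFLI1 replicate 1 and 0.02 (adjusted p = 0.19) without siFLI1 replicate 2. Without siEWSR1 replicate 1 the calls of repressed targets, matrix, interferon and blood cell markers ended (0.0721, 0.0949, 0.0792 and 0.0978), as did cholesterol without siEWSR1 replicate 2 (median -0.07, 0.17) and interferon (median -0.09) and blood cell markers without siFLI1 replicate 1 (0.132 and 0.0884). Medians also moved to -0.28 for repressed targets without siEWSR1 replicate 2, to -0.28 for cholesterol without siEWSR1 replicate 1 and to 0.13 for histones without siFLI1 replicate 1, and these calls held at the preset correlation.

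FLI1 fell by 0.29 on the log2 scale with siFLI1, and did not pass the threshold with siEWSR1, while 331 genes rose and 38 fell at least 4-fold with siFLI1. Library scaling is argued against, since the lowest FLI1 change over both other scalings was -0.388. Reads of overlapping genes cannot be ruled out fully. The FPKM of LOC101929538 and SENCR, named after their values were seen, added up to at most 1.1% of the FLI1 FPKM in a siFLI1 library. Where these genes overlap FLI1, however, their reads cannot be told apart from its own. The deposited intervals leave no room for a halving by counting error, as the lower of the lower bounds was 73.2% of the siNeg mean. Whether cleaved transcript remained in the libraries, whether protein fell more than RNA, or whether normal and fusion transcripts changed differently stays open, as gene-level FPKM does not separate them.

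Of 8 measured histone genes 6 rose with siEWSR1 and 5 with siFLI1, while 31 of 38 DNA replication genes fell with each; the histone list's call was lost with an estimated correlation (adjusted p = 0.478 and 0.541) and with low genes kept (medians 0.26 and 0.29, adjusted p = 0.0697 and 0.166). A larger share of RNA without a poly(A) tail in the knockdown libraries cannot be told apart from a change in histone expression: 4 of 14 listed RNAs of that kind were measured, too few and too scattered to decide, and the higher of their median log2 changes was 0.215. The 6 listed histone genes below the level filter had medians of -0.07 and 0.10 (the higher is 0.099). A histone gene that rose well past the filter could not be among them, and their levels were near the floor. These 6 genes therefore cannot decide whether all histone genes rose. Some histone genes are known to also make polyadenylated transcripts in cells that leave the cycle, which was not tested.

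siEWSR1 lay below siFLI1 in most genes that differed. Library scaling alone is argued against, since at least 1.641 genes were lower for each gene higher under both other scalings, though the share of higher calls moved from 20.4% to 37.9% with quantile normalization. Whether a single library sets this split cannot be told apart, as the ratio without siFLI1 replicate 2 was 0.333 but on 4 calls, too few to read. Whether siFLI1 gave a larger response in every responsive gene cannot be decided. With all libraries, of the 932 higher at least 2-fold with both siRNAs, 117 were called as changing less with siEWSR1 and 20 as changing more. The threshold allows some false calls among the 504 direct ones, and direct calls were far fewer without either siFLI1 library. A larger response to siFLI1 in most genes stays open, as 69.6% of the 932 changed less with siEWSR1, with a median difference of -0.12. Of the 499 lower at least 2-fold with both, 60.5% changed less with siEWSR1, and 1 was called each way. Their median difference was 0.033, which ran from -0.07 to 0.12 as single libraries were left out. Whether siEWSR1 lowered normal EWSR1, the fusion or both was not tested, as gene-level FPKM does not separate their transcripts.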

How the results depend on the processing

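The restriction to genes that overlap no other expressed gene and the split of the siNeg libraries between the comparisons were chosen after seeing the data; all other alternatives were set before. With 2 libraries per group, a left-out library leaves 1, assumed to vary as the others do. Counts against siNeg stayed within 1.5 times, except that with a mean FPKM of at least 5 the genes higher were 2518 (siEWSR1), 2787 (siFLI1) and 2263 (both), as fewer genes were tested. With a log2 change of at least 1 they were 1032 higher and 599 lower (siEWSR1), 1215 and 599 (siFLI1), and 932 and 499 (both), the direct counts were 6 and 26, and the falls of EWSR1 (-0.48) and FLI1 (-0.29) did not reach that size. The direct counts of siEWSR1 against siFLI1 moved most: 15 higher and 73 lower with no filter, 209 higher with quantile normalization, 185 and 640 with a robust trend, 12 and 99 with only the 2 groups compared, and 159 higher without overlapping genes. Leaving out 1 library gave 3 to 107 higher and 1 to 621 lower. Without siNeg replicate 1 or 2, which do not enter the difference, they were 15 and 109 or 15 and 119, so the counts fell there while the differences stayed the same. The cause of the other moves was not tested.

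Replicate numbers are shared between groups, but nothing says that they pair libraries, and the differences between replicates 1 and 2 correlated across genes at -0.137, -0.053 and 0.069 between groups. With the replicate block the direct counts were 57 higher and 262 lower; the other counts stayed within 1.5 times, and the EWS-FLI1-activated list became higher with siEWSR1 than with siFLI1 (adjusted p = 0.0326).

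Among results called with all libraries or in the alternative, direction turned for KRT14 under quantile normalization (-0.011 and -0.066 for siEWSR1 and siFLI1) and, directly compared without siEWSR1 replicate 1, for the mitosis (median -0.058), DNA replication (-0.124) and hypoxia (-0.25) lists, which stood at 0.186, 0.101 and 0.22 without siEWSR1 replicate 2. For DNA replication it was camera's direction that turned, as the median was already -0.003. Of results called in neither, 30 differed in sign (camera's direction for lists). The cause was not tested. With an estimated correlation, 30 of 60 list tests lost their call and the other 30 stayed uncalled. The blood cell list gave no value with a mean FPKM of at least 5, as no member was left. Depth limits low genes, as 1 or a few fragments set their values.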

Other observations

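The groups in this part were chosen after the main results were seen, and so were the tests, except that of the aminoacyl-tRNA synthetases, whose levels had not been examined. Lysosomal genes rose with both siRNAs: of 28 measured, 23 rose and 1 fell with siEWSR1 (median log2 change 0.68, camera adjusted p = 6.38e-06; adjusted p = 0.419 with an estimated correlation), and 25 rose and 0 fell with siFLI1 (0.91, adjusted p = 1.72e-06; adjusted p = 0.497 with an estimated correlation). PSAP, the precursor of sphingolipid activator proteins, went from 159 FPKM with siNeg to 395 and 412 with siEWSR1 and siFLI1, and CTSD, a lysosomal protease, from 44.8 to 129 and 152. Of 14 imprinted genes 9 rose and 3 fell with siEWSR1 (adjusted p = 0.0154; adjusted p = 0.419 with an estimated correlation), and 10 rose and 1 fell with siFLI1 (adjusted p = 0.00122; adjusted p = 0.481 with an estimated correlation). H19, already seen to rise 193-fold and 174-fold, is 1 of these 14 genes, so the p-values of this list partly restate that rise. MEG3 went from 2.38 FPKM to 18.8 and 21.8, and CDKN1C, a cell cycle inhibitor, from 1.93 to 15 and 29.9.

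Of 25 measured HOX genes 13 fell and 5 rose with siEWSR1 (camera adjusted p = 0.0769), and 14 fell and 4 rose with siFLI1 (adjusted p = 0.0025; adjusted p = 0.644 with an estimated correlation). HOXD10 went from 76.8 FPKM to 35.1 and 31.1 and HOXD4 from 39.4 to 12 and 11.9, whereas HOXB13 was slightly higher, at 79.8, 93.5 and 93.1. MHC class I presentation genes moved both ways, with 3 of 14 higher and 3 lower with siEWSR1 (adjusted p = 0.766) and 5 higher and 2 lower with siFLI1 (adjusted p = 0.493). Of 6 metallothioneins, whose reads are hard to separate, 5 rose and 1 fell with siEWSR1 (adjusted p = 0.116), and 3 rose and 1 fell with siFLI1 (adjusted p = 0.589). Compared directly, siEWSR1 lay above siFLI1 in the medians of metallothioneins (0.24, adjusted p = 0.00103; 0.344 with an estimated correlation) and HOX genes (0.14, 0.000567; 0.458). It lay below in lysosomal (-0.12, 0.00487; 0.458), imprinted (-0.19, 0.0442; 0.418) and MHC class I genes (-0.09, 0.0442; 0.418).

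ATF4 target genes fell with both siRNAs, and a lower amino acid response is a candidate explanation. It predicts lower cytosolic aminoacyl-tRNA synthetases, which that response raises. Of 20 measured, 16 fell and 1 rose with siEWSR1 and 15 fell and 2 rose with siFLI1, and the higher of the median log2 changes was -0.954 (adjusted p = 5.86e-06 and 1.72e-06; 0.419 and 0.54 with an estimated correlation). GARS went from 199 FPKM to 49.1 and 49.4. Synthetase genes can be ATF4 targets themselves, so their fall may restate the pattern and cannot single out an amino acid response. A lower unfolded protein response as a whole is argued against, as endoplasmic reticulum chaperones, 6 of 16 higher and 3 lower with each siRNA and 3 of the 16 also in a list fixed earlier, had medians up to 0.105. Whether the siNeg cultures had used up more amino acids, for example by growing denser, was not tested.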
